A study of Salmo salar with 48 samples.

How the data were processed

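The series holds bisulfite amplicon sequencing of liver DNA from 48 Atlantic salmon. Per the labels' protocols, DNA was extracted from each liver, converted with a bisulfite kit, amplified, indexed with a Nextera XT kit and sequenced on an Illumina MiSeq. The submitters' processing notes name Trim Galore 0.4.4, MultiQC 1.9, Bismark 0.20.0 and Bowtie2, the last without a version. Their settings, the treatment of duplicate reads, the name of the genome build and the measured conversion rate were not given in the sources used here.

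The deposited file of each fish lists, per the file headers, the counts of methylated and unmethylated calls at each CpG cytosine with its reference sequence, position and strand. The unit is whole-number counts, without normalization. Only cytosines with at least 1 call are listed. The sample name inside each file matched the title of its fish in all 48 files. The group, sex and tank of a fish were taken from its title and characteristics. That each file is a separate fish is taken from the labels. The counts of the closest 2 fish of a group, warm hypoxic fish of 3 days, differed with a chi-square of 38.5 per CpG, a measure that treats PCR reads as independent and so covers counting error only.

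Regions were defined as runs of CpGs with calls in every fish that lay less than 1000 bp apart. All 161814384 calls at these CpGs were on the plus strand. A level is 100 times the methylated calls over all calls, and a CpG was used in a fish with at least 30 reads. Chromosome numbers follow the names of the reference sequences. The gene table at hand belongs to another assembly, so its positions were not used and the regions carry no gene names. The gene lists fixed beforehand could therefore not be applied, and each region is reported on its own.

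The tests were fixed before the data were examined. For each comparison, CpGs with 30 reads in at least 6 fish of each group were tested by the difference between the groups' mean levels, with fish weighted equally. The plan named a quasi-binomial logistic model with equal weights, whose fitted values are these means, but the model itself was not fitted. The two-sided p came from all 12870 splits of the 16 fish, with a smallest possible value of 0.000155. P-values were adjusted by Benjamini-Hochberg over the CpGs of a comparison, with a threshold of 0.05. Region means were unweighted means over CpGs with 30 reads in at least 40 fish, tested with the same exact permutation test and adjusted over the 6 regions of a comparison. The 95% intervals hold the shifts that this test did not reject. Time dependence was tested by permuting residuals of the additive model of treatment and time, and sex by permuting within the 6 groups, each with 100000 resamples. P-values measure the spread between fish. Because each treatment was applied to 2 tanks, they do not include differences between tanks.

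The text names all regions. In each comparison of treatments it names the CpGs past the threshold, at most the 10 with the largest difference, or, where fewer than 3 pass, the 3 with the smallest p. In the comparisons of times and sexes it was set to name at most the 5 largest past the threshold, of which there were none.

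The alternatives fixed beforehand were coverage minimums of 10 and 100 reads, a coverage-weighted logistic model with an exact test, limma on M-values, log2((methylated + 1) / (unmethylated + 1)), over all 6 groups without and with tank as a random block, permutation within sex, separate strands, leaving out CpGs in which 2 fish of a group differed by more than 40 points (1 CpG), leaving out each tank, and for the times a permutation within tanks. Added after the data were seen were limma with the tank block for the region means, leaving out each tank for the region means, leaving out the 3 fish with the most calls outside the regions (in the time dependence too), weighting fish by their reads in the time dependence of the region means, adjustment over all 54 region tests, leaving out each fish that stood apart from its group, and limma on tank means of M-values. The last was fitted over the 6 tanks of each time and over the 12 tank means of both times, where the 2 times of a tank were treated as separate.

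The tests were checked on simulated counts with the coverage, levels and spread of the real fish, for warm hypoxic against control fish at 4 weeks. Each CpG of a fish was drawn separately, and no differences between tanks were simulated. In some regions the CpGs of the real fish vary together, as described below. The recovered shares and the calls at unshifted CpGs hold for CpGs that vary separately. How they change where CpGs vary together was not simulated. With 20 of 94 CpGs shifted, the exact test recovered 7.0% of them at a shift of 1 SD of the fish, 74.7% at 2 SD and 96.0% at 3 SD, over 30 repeats each, and 5.27% or less of the unshifted CpGs had an unadjusted p under 0.05. Calls at unshifted CpGs averaged 0.633 per repeat or fewer. Shifting 20 CpGs at once eases the adjustment over the 94. These shares therefore overstate the recovery of a CpG shifted alone, which was not simulated. With the levels of ssa03 and ssa16 both lowered by 50%, which eases the adjustment over the 6 regions, the fall at ssa03 was recovered in 93.3% of the repeats. With ssa03 lowered alone it was recovered in 96.7% of 30 repeats at 50% and in 40% of them at 30%, where the fall seen in the fish was -31.1% of the control level. On a simulated set with shifts of 3 SD, limma recovered 95% of the 20 CpGs. In these simulations a shift of 1 SD at a CpG was thus mostly not detected with 8 fish per group, even with 20 CpGs shifted together.

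Calculations used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and R 4.3.3 with limma 3.58.1 and statmod 1.5.0. Plots were drawn with matplotlib 3.10.9.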

Results

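DNA methylation was measured in the liver of 48 juvenile Atlantic salmon (Salmo salar) from a commercial broodstock of the St. John River strain. The fish belonged to 3 treatments. Control fish (CT) were kept at 12 °C and 100% air saturation. Warm normoxic fish (WN) were warmed from 12 to 20 °C in steps of 1 °C per week at 100% air saturation. Warm hypoxic fish (WH) were first brought to 70% air saturation and then warmed along the same ramp. Livers were taken after 3 days and after 4 weeks at 20 °C, or from control fish at the same times, with 8 different fish in each of the 6 groups. Each group drew 4 fish from each of 2 tanks, and the same 2 tanks of a treatment were sampled at both times. Of the fish, 23 were male and 25 female. The groups ranged from 2 males and 6 females (CT at 3 days and WH at 4 weeks) to 5 males and 3 females (CT at 4 weeks, WN at 4 weeks and WH at 3 days).

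Bisulfite-converted DNA was amplified at chosen regions and sequenced, so that the methylation level of a CpG is the percentage of reads in which its cytosine was still read as C. Calls fell on 107 CpGs in 7 regions that were covered in every fish. A fish had between 1939550 and 4890736 calls at these CpGs, with a median of 3251826. The groups' medians lay between 2992402 (WN at 3 days) and 3574344 (WH at 3 days). The mean number of calls was 3372057 ± 684327 (SD, n = 24) in fish of 4 weeks and 3370209 ± 572932 (SD, n = 24) in fish of 3 days (permutation p = 0.993, two-sided).

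Regions are named by their chromosome, ssa being the usual prefix for salmon chromosomes, and positions are those of the reference sequences named in the files. Region ssa03 spans positions 13688232 to 13688647 of chromosome 3 (NC_027302.1) with 16 CpGs. Chromosome 4 (NC_027303.1) carries a region of 18 CpGs at 35435825 to 35436217, called ssa04 (35 Mb), and one of 15 CpGs at 44947109 to 44947524, called ssa04 (45 Mb). Region ssa09 has 8 CpGs at 121687029 to 121687311 of chromosome 9 (NC_027308.1). Region ssa14 has 14 CpGs at 33502562 to 33502977 of chromosome 14 (NC_027313.1). Region ssa15 has 13 CpGs at 46698401 to 46698820 of chromosome 15 (NC_027314.1), and ssa16 has 23 CpGs at 37941696 to 37942102 of chromosome 16 (NC_027315.1). The genes at these positions were not analysed here, because the gene table at hand belongs to another assembly than these reference sequences.

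The regions fell into 3 ranges of methylation. Region ssa09 was almost fully methylated, at 92.3% ± 1.17 (SD, n = 48 fish), with CpG means from 85.8% to 96.5%. Region ssa04 (35 Mb) was intermediate, at 26.6% ± 4.78 (SD, n = 48), and its CpGs ranged from a mean of 2.43% at 35436037 to 63.0% at 35435919. The remaining regions had low levels. Their means were 0.692% ± 0.149 at ssa03, 0.505% ± 0.140 at ssa04 (45 Mb), 1.36% ± 0.458 at ssa14 and 0.539% ± 0.0541 at ssa16 (SD, n = 48 each). Within ssa14 the first CpG, at 33502562, was highest, with 5.03% ± 2.00 (SD, n = 48), and the last, at 33502977, had 0.489% ± 0.307 (SD, n = 48). Cytosines that escaped conversion are read as methylated and are part of these low levels. Their share was not measured, since the calls cover CpG cytosines only.

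Depth differed strongly between regions. The median fish had 89498 reads per CpG at ssa09, 74080 at ssa04 (35 Mb), 31458 at ssa14, 25178 at ssa04 (45 Mb) and 10434 at ssa16. At ssa03 the median fish had 436 reads per CpG and the fish ranged from 160 to 21254. At ssa15 the median was 18.5 reads, and 21 of the 48 fish reached 30 reads. The counts are of PCR reads and not of molecules, so read numbers overstate the independent observations, and the errors given here are the spread between fish. The remaining 94 CpGs in 6 regions were tested.

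**Figure D1:**
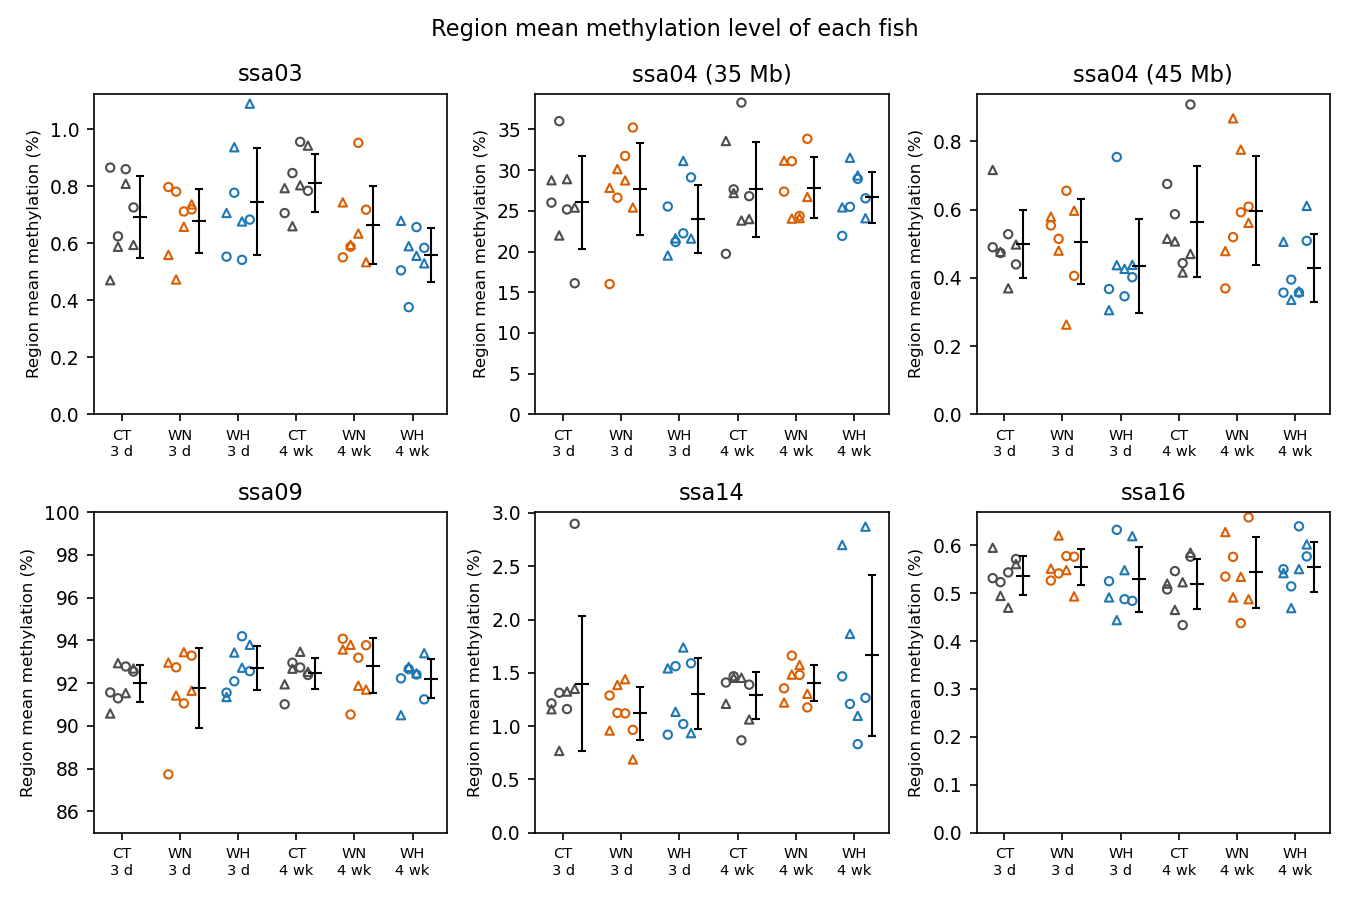
Region mean methylation level (%, vertical axis) of each fish in the 6 tested regions, by treatment (CT control, WN warm normoxic, WH warm hypoxic) and time of sampling, in days or weeks after the warm fish reached 20 °C. Open points are fish, circles and triangles mark the 2 tanks of a treatment, and the black bar with whiskers is the group mean ± SD of 8 fish. The ssa09 axis starts at 85%. In ssa03 at 4 weeks, 7 of the 8 WH fish (group mean 0.560%) lie below every CT fish (group mean 0.812%).

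The first comparison asked what warming did when oxygen stayed at saturation. After 3 days at 20 °C, no region mean differed past the threshold between warm normoxic and control fish. The intermediate region ssa04 (35 Mb) stood at 27.7% ± 5.65 in warm normoxic and 26.0% ± 5.75 in control fish (SD, n = 8 each), a difference of 1.67 percentage points with a 95% interval of -4.50 to 7.69 (exact permutation p = 0.564, two-sided). Region ssa09 stood at 91.8% ± 1.87 and 92.0% ± 0.859, and ssa03 at 0.680% ± 0.112 and 0.692% ± 0.145 (SD, n = 8 each). The ssa09 difference of -0.203 points was 0.376 points without warm normoxic fish 77 (exact permutation p = 0.430, adjusted p = 0.645). The ssa03 difference of -0.0127 points was -0.129 points in the coverage-weighted model (exact permutation, adjusted p = 0.896). The smallest adjusted p of the 6 region means was 0.901 (exact permutation, Benjamini-Hochberg over regions). Of the 94 CpGs, 0 passed the threshold in the exact permutation test, 0 in the limma fits and 0 in the coverage-weighted model. Unadjusted p-values under 0.05 occurred at 7 CpGs, where 4.7 would be expected by chance. The 3 CpGs with the smallest p are therefore named as not past the threshold. At ssa16 position 37941770 the level was 0.479% ± 0.219 in warm normoxic and 0.256% ± 0.0634 in control fish, a difference of 0.223 points (SE 0.0805, n = 8 each, exact p = 0.00482, adjusted p = 0.368). At ssa09 position 121687082 it was 96.5% ± 0.757 against 95.6% ± 0.416, a difference of 0.879 points (SE 0.306, n = 8 each, exact p = 0.0143, adjusted p = 0.368). Position 13688404 of ssa03 had 0.884% ± 0.326 against 0.318% ± 0.439, a difference of 0.566 points (SE 0.193, n = 8 each, exact p = 0.0154, adjusted p = 0.368). Without control fish 84 this difference was 0.702 points (exact permutation p = 0.00124, adjusted p = 0.117).

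At 3 days none of the 6 region means differed past the threshold between warm hypoxic and control fish. Region ssa04 (35 Mb) had 24.0% ± 4.17 in warm hypoxic fish against 26.0% ± 5.75 in controls (SD, n = 8 each), a difference of -2.05 points with a 95% interval of -7.29 to 3.27 (exact permutation p = 0.429, two-sided). At ssa09 the levels were 92.7% ± 1.03 and 92.0% ± 0.859, a difference of 0.723 points (SE 0.475, n = 8 each, exact p = 0.149, adjusted p = 0.804). Region ssa03 had 0.746% ± 0.187 and 0.692% ± 0.145 (SD, n = 8 each), a difference of 0.0535 points that was -0.233 points in the coverage-weighted model (exact permutation, adjusted p = 0.237). The difference at ssa04 (45 Mb) was -0.0642 points. It was -0.110 points without warm hypoxic fish 74 (exact permutation p = 0.00963, adjusted p = 0.0578) and -0.0331 points without control fish 85 (adjusted p = 0.963). In the exact permutation test 0 of the 94 CpGs passed, and 0 in the limma fits, with 7 at an unadjusted p under 0.05 in the former. The coverage-weighted model called 1 CpG, the first of those named next. At ssa09 position 121687082, which had at least 34739 reads in each of these fish, the level was 96.7% ± 0.823 in warm hypoxic and 95.6% ± 0.416 in control fish, a difference of 1.12 points with a 95% interval of 0.415 to 1.82 (n = 8 each, exact p = 0.00373, adjusted p = 0.343, against 0.0438 in the coverage-weighted exact test). Position 13688501 of ssa03 had 1.01% ± 0.824 against 0.321% ± 0.257, a difference of 0.685 points (SE 0.305, n = 8 each, exact p = 0.00730, adjusted p = 0.343). It was 0.330 points in the coverage-weighted model and 0.420 points without warm hypoxic fish 94 (exact permutation p = 0.0146, adjusted p = 0.456). Position 44947155 of ssa04 (45 Mb) had 0.233% ± 0.0702 against 0.701% ± 0.798, a difference of -0.468 points (SE 0.283, n = 8 each, exact p = 0.0113, adjusted p = 0.355). In the last of these, the highest control fish, fish 85, had 2.61% and the next 0.775%, and without fish 85 the difference was -0.196 points (exact permutation p = 0.0174, adjusted p = 0.409).

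Set against each other at 3 days, warm hypoxic and warm normoxic fish differ in treatment by their air saturation. Their region means did not differ past the threshold. The widest gap in points was at ssa04 (35 Mb), with 24.0% ± 4.17 in warm hypoxic and 27.7% ± 5.65 in warm normoxic fish (SD, n = 8 each). It came to -3.73 points with a 95% interval of -8.91 to 1.64 (exact permutation p = 0.154, adjusted p = 0.418). The ssa04 (45 Mb) difference of -0.0714 points was -0.117 points without warm hypoxic fish 74 (exact permutation p = 0.0390, adjusted p = 0.234). All 94 CpGs stayed short of the threshold in the exact permutation test, the limma fits and the coverage-weighted model, and 5 had an unadjusted p under 0.05. The smallest p belonged to ssa14 position 33502632, with 1.26% ± 0.522 against 0.537% ± 0.428, a difference of 0.726 points (SE 0.239, n = 8 each, exact p = 0.0115, adjusted p = 0.721). At ssa16 position 37941700 the levels were 0.572% ± 0.269 and 0.907% ± 0.225, a difference of -0.334 points (SE 0.124, n = 8 each, exact p = 0.0207, adjusted p = 0.721). At position 35436020 of ssa04 (35 Mb) they were 13.5% ± 3.63 and 18.9% ± 4.95, a difference of -5.44 points (SE 2.17, n = 8 each, exact p = 0.0274, adjusted p = 0.721).

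**Figure D2:**
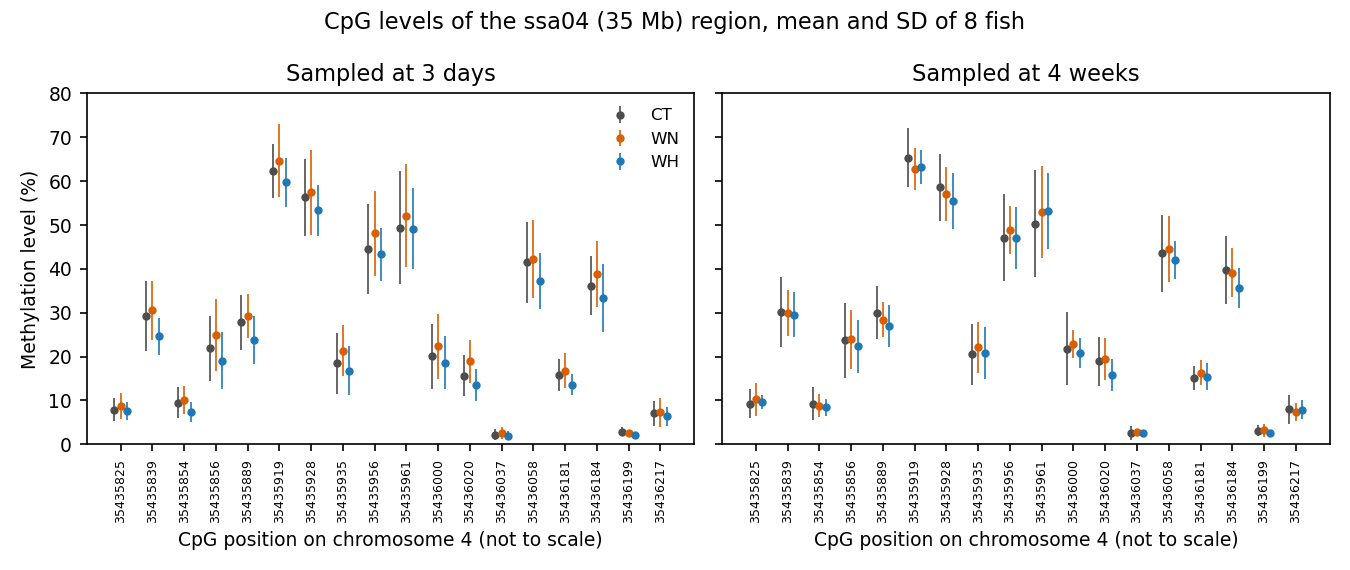
Methylation level (%, vertical axis) of the 18 CpGs of the ssa04 (35 Mb) region in CT, WN and WH fish sampled when the warm fish had been at 20 °C for 3 days (left) and 4 weeks (right). Points are means and lines are the SD of 8 fish. Positions are evenly spaced, not to scale. The CpGs range from about the 2.43% mean at 35436037 to the 63.0% mean at 35435919.

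After 4 weeks at 20 °C no region mean differed past the threshold between warm normoxic and control fish. Region ssa04 (35 Mb) had 27.8% ± 3.77 in warm normoxic and 27.6% ± 5.86 in control fish, and ssa09 had 92.8% ± 1.28 and 92.5% ± 0.732 (SD, n = 8 each). Region ssa03 was 0.665% ± 0.138 in warm normoxic and 0.812% ± 0.103 in control fish, a difference of -0.147 points with a 95% interval of -0.274 to -0.0146 (n = 8 each). Its exact permutation p of 0.0333 became 0.1995 after adjustment over the 6 regions, and in the coverage-weighted model the difference was -0.234 points (exact permutation p = 0.0306, adjusted p = 0.184). Of the 94 CpGs, 0 passed in the exact permutation test, 0 in the limma fits and 0 in the coverage-weighted model, and 4 had an unadjusted p under 0.05. Position 44947115 of ssa04 (45 Mb) had 0.213% ± 0.0350 against 0.893% ± 1.06, a difference of -0.680 points (SE 0.376, n = 8 each, exact p = 0.00311, adjusted p = 0.292). With a minimum of 100 reads, which removes control fish 108 with 58 reads and 3.45% there, this difference was -0.315 points. At ssa14 position 33502764 the levels were 1.81% ± 1.23 and 0.827% ± 0.449, a difference of 0.981 points (SE 0.462, n = 8 each, exact p = 0.0132, adjusted p = 0.584), which was 0.570 points without warm normoxic fish 102 (exact permutation p = 0.0260, adjusted p = 0.813). Position 13688533 of ssa03 had 0.245% ± 0.224 against 0.902% ± 0.633, a difference of -0.657 points (SE 0.237, n = 8 each, exact p = 0.0204, adjusted p = 0.584), and its difference was -0.341 points in the coverage-weighted model.

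The comparison of warm hypoxic with control fish at 4 weeks gave the 1 region mean past the threshold. Region ssa03 was lower in warm hypoxic fish, at 0.560% ± 0.0948, than in control fish, at 0.812% ± 0.103 (SD, n = 8 each). The difference was -0.252 percentage points with a 95% interval of -0.359 to -0.146 (exact permutation p = 0.000311, two-sided, adjusted p = 0.00186 over the 6 regions). All 8 warm hypoxic fish lay below the control mean, and 7 of the 8 lay below every control fish. The lower level was spread over the region, with 14 of its 16 CpGs lower in warm hypoxic fish and differences from -0.705 to 0.260 points. The tank means were 0.531% and 0.589% in the 2 warm hypoxic tanks and 0.823% and 0.8001% in the 2 control tanks (n = 4 fish each). The levels rest on a median of 51 methylated calls per fish in warm hypoxic and 72 in control fish over all CpGs of the region. Across all 54 region tests of the 9 comparisons this was the one with an adjusted p under the threshold (exact permutation, adjusted p = 0.0168 over the 54). These p-values treat fish as the unit. With tank means as the unit, in limma fits added after the data were seen, the adjusted p of this difference was 0.0103 over the 6 tanks of 4 weeks and 0.0899 over the 12 tank means of both times, which missed the threshold.

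The other regions did not pass the threshold in this comparison. Region ssa04 (45 Mb) had 0.428% ± 0.100 in warm hypoxic and 0.565% ± 0.161 in control fish, a difference of -0.136 points (SE 0.0672, n = 8 each, exact p = 0.0511, adjusted p = 0.153). Without the 3 fish that had the most calls outside the regions, an alternative chosen after the data were seen, this difference was -0.162 points (exact permutation, adjusted p = 0.0466). It was -0.0754 points in the coverage-weighted model, -0.0851 within sex, -0.0873 with a minimum of 100 reads, which removes fish 108, -0.0481 without control tank T3 and -0.225 without control tank T4 (exact permutation, adjusted p from 0.0545 to 0.507). Region ssa16 had 0.555% ± 0.0522 against 0.519% ± 0.0516, a difference of 0.0360 points with a 95% interval of -0.0199 to 0.0920 (n = 8 each, exact p = 0.189). Region ssa14 had 1.66% ± 0.755 against 1.29% ± 0.223 (SD, n = 8 each, exact permutation p = 0.231). Its difference of 0.374 points was 0.844 points without tank T1 of the warm hypoxic fish (exact permutation, adjusted p = 0.0424) and -0.0959 points without their tank T6. At ssa04 (35 Mb) the levels were 26.7% ± 3.12 and 27.6% ± 5.86, a difference of -0.969 points with a 95% interval of -6.04 to 3.94, and at ssa09 they were 92.2% ± 0.916 and 92.5% ± 0.732 (SD, n = 8 each).

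Single CpGs did not pass in this comparison. In the exact permutation test, the limma fits and the coverage-weighted model 0 of 94 CpGs passed, and 2 had an unadjusted p under 0.05 in the first of these. At ssa16 position 37941700 the level was 0.907% ± 0.314 in warm hypoxic and 0.552% ± 0.213 in control fish, a difference of 0.355 points (SE 0.134, n = 8 each, exact p = 0.0193, adjusted p = 0.866). At ssa03 position 13688533 it was 0.277% ± 0.294 against 0.902% ± 0.633, a difference of -0.625 points (SE 0.247, n = 8 each, exact p = 0.0284, adjusted p = 0.866), which was -0.234 points in the coverage-weighted model. Position 33502773 of ssa14 had 0.919% ± 0.269 against 0.649% ± 0.336, a difference of 0.270 points (SE 0.152, n = 8 each, exact p = 0.0996, adjusted p = 0.866). Without control fish 107 this difference was 0.385 points (exact permutation p = 0.00218, adjusted p = 0.205).

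**Figure D3:**
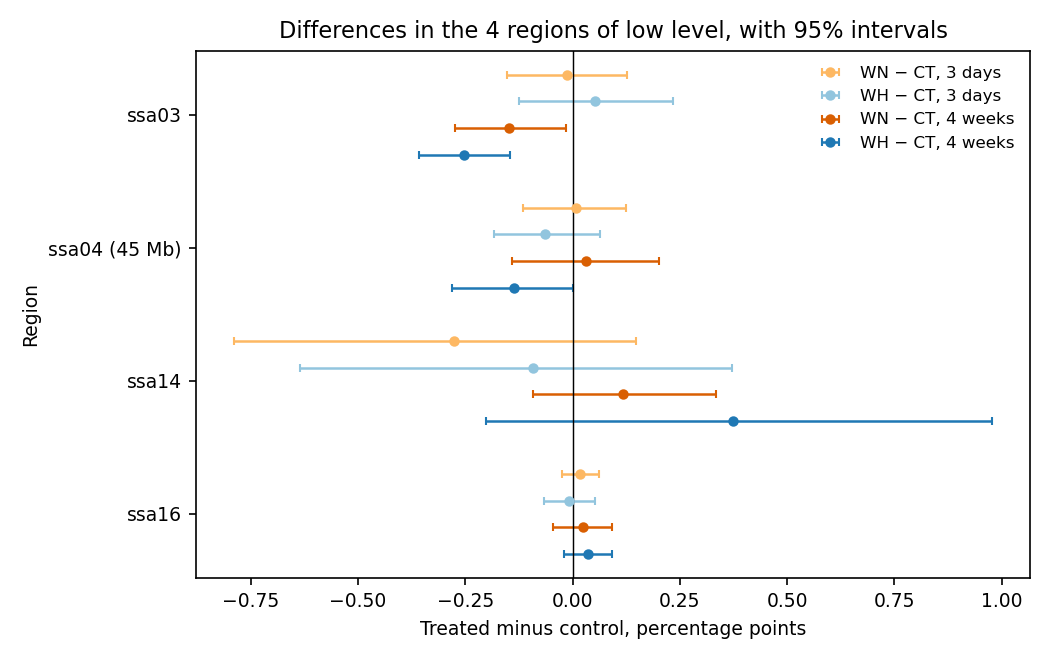
Differences in region mean methylation level between treated and control fish (percentage points, horizontal axis) for the 4 regions of low level, in WN and WH fish at 3 days and 4 weeks. Points are differences of the means of 8 against 8 fish, and bars are 95% intervals from the exact permutation test. The interval of ssa03 in WH fish at 4 weeks runs from -0.359 to -0.146, and that of ssa16 in the same fish from -0.0199 to 0.0920.

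At 4 weeks the warm hypoxic and warm normoxic fish differed in no region mean past the threshold. The lowest p belonged to ssa04 (45 Mb), with 0.428% ± 0.100 in warm hypoxic and 0.596% ± 0.160 in warm normoxic fish, a difference of -0.168 points with a 95% interval of -0.312 to -0.0262 (n = 8 each, exact p = 0.0246, adjusted p = 0.147). Without the 3 fish that had the most calls outside the regions it was -0.226 points (exact permutation, adjusted p = 0.0140), and without tank T5 of the warm normoxic fish -0.0937 points (adjusted p = 0.448). Region ssa03 had 0.560% ± 0.0948 against 0.665% ± 0.138, a difference of -0.105 points (n = 8 each, exact p = 0.0936, adjusted p = 0.281) that was -0.0149 points in the coverage-weighted model (exact permutation p = 0.792). At ssa04 (35 Mb) the levels were 26.7% ± 3.12 and 27.8% ± 3.77 (SD, n = 8 each, exact permutation p = 0.4999). In the exact permutation test 0 of the 94 CpGs passed, with 0 in the limma fits and 0 in the coverage-weighted model, and 3 had an unadjusted p under 0.05. These 3 were ssa14 position 33502814, with 1.14% ± 0.476 against 0.683% ± 0.152 (difference 0.457 points, SE 0.177, n = 8 each, exact p = 0.0135), ssa04 (45 Mb) position 44947115, with 0.756% ± 0.737 against 0.213% ± 0.0350 (difference 0.543 points, SE 0.261, exact p = 0.0165), and ssa14 position 33502876, with 0.632% ± 0.267 against 1.02% ± 0.350 (difference -0.387 points, SE 0.156, exact p = 0.0284). Their adjusted p-values were 0.774, 0.774 and 0.891 (exact permutation). Without warm hypoxic fish 120 the difference at 44947115 was 0.308 points (exact permutation p = 0.0165, adjusted p = 0.726).

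Treatment was applied to tanks, and an exact permutation that exchanges 2 tanks with 2 has a smallest two-sided p of 0.333. In the limma fits on tank means the ssa03 difference of warm hypoxic from control fish at 4 weeks, over the tanks of that time, was the 1 region result past the threshold. The correlation between fish of one tank that limma estimated was -0.0627 over the CpGs and -0.0180 over the region means. Each is 1 value for all features, drawn from 2 tanks per treatment, and does not show that tanks were alike at ssa03. There the 2 tanks differed at 3 days by 0.154 points in control, 0.146 in warm normoxic and 0.214 in warm hypoxic fish. At 4 weeks the gaps were 0.0233, 0.0758 and 0.0582 points, with the same tank higher at both times. In 21 of the 36 combinations of a treatment comparison and a region, both tanks of one treatment lay on the same side of both tanks of the other, where 12 would be expected by chance. The combinations share tanks and are not independent, so how far chance moves this count from 12 is not known. The 18 named CpGs all showed this order of tanks, but they were chosen for their small p.

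Time at 20 °C was compared within each treatment, in the same tanks. Control fish had no region mean or CpG past the threshold between 3 days and 4 weeks. Their ssa03 level was 0.812% ± 0.103 at 4 weeks and 0.692% ± 0.145 at 3 days, a difference of 0.119 points (SE 0.0629, n = 8 each, exact p = 0.0797, adjusted p = 0.478) that was 0.0170 points in the coverage-weighted model (exact permutation, adjusted p = 0.766). Without tank T3 of the control fish of 3 days this difference was 0.196 points (exact permutation p = 0.0263, adjusted p = 0.158), and without their tank T4 0.0426 points. In warm normoxic fish the smallest p was at ssa14, with 1.41% ± 0.171 at 4 weeks and 1.12% ± 0.250 at 3 days, a difference of 0.286 points (SE 0.107, n = 8 each, exact p = 0.0180, adjusted p = 0.108). In warm hypoxic fish ssa03 had 0.560% ± 0.0948 at 4 weeks and 0.746% ± 0.187 at 3 days, a difference of -0.186 points with a 95% interval of -0.347 to -0.0311 (n = 8 each, exact p = 0.0174, adjusted p = 0.104). This last difference passed the threshold when fish were exchanged within sex (-0.215 points, exact permutation, adjusted p = 0.00340) and in limma (adjusted p = 0.0436, and 0.0492 with the tank block), and it was 0.00143 points in the coverage-weighted model. Without tank T1 of the fish of 3 days it was -0.293 points (exact permutation, adjusted p = 0.0242), and without their tank T6 -0.0794 points. The intermediate region ssa04 (35 Mb) differed between the times by 1.59 points in control (SE 2.90, n = 8 each, exact permutation p = 0.594), 0.124 points in warm normoxic (SE 2.40, p = 0.962) and 2.67 points in warm hypoxic fish (SE 1.84, p = 0.167, adjusted p = 0.462). In warm hypoxic fish all 18 of its CpGs were higher at 4 weeks, but the CpGs of this region vary together between fish and are not separate observations. The CpGs past the threshold numbered 0 of 94 in each of the 3 time comparisons in the exact permutation test, the limma fits, the coverage-weighted model and the permutation within tanks. Unadjusted p-values under 0.05 in the exact test occurred at 3 CpGs in control, 3 in warm normoxic and 7 in warm hypoxic fish.

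Whether the treatment difference itself changed between the times was tested directly. For ssa03 the warm hypoxic minus control difference was 0.0535 points at 3 days and -0.252 points at 4 weeks, a change of -0.306 points (permutation p = 0.00230, adjusted p = 0.0138 over the 6 regions). Both groups contributed, with 4 weeks minus 3 days at 0.119 points in control and -0.186 points in warm hypoxic fish. Neither passed the threshold in the exact test, and control fish of 4 weeks had the highest ssa03 mean of the 6 groups. The limma interaction term for this region had an adjusted p of 0.0137. These p-values treat fish as the unit, and the change was not fitted on tank means. With single tanks left out, the difference at 3 days ran from -0.0533 to 0.160 points. With fish weighted by their reads, an alternative added after the data were seen, the change was -0.0156 points (permutation p = 0.804, adjusted p = 0.892). The coverage-weighted difference was -0.233 points at 3 days (exact permutation, adjusted p = 0.237) and -0.249 points at 4 weeks (adjusted p = 0.00280). Weighting by reads gives the deepest fish the most weight. At 3 days the deepest control fish, fish 83, had 21254 reads per CpG and a level of 0.860%, where its group's median was 396.5 reads. The deepest warm hypoxic fish of that time, fish 75, had 14776.5 reads and 0.542%, where its group's median was 702.5 reads. For the warm normoxic minus control difference the change at ssa03 was -0.134 points (permutation p = 0.129, adjusted p = 0.386), and no region passed. For either treatment 0 of the 94 CpGs passed in the permutation test or in limma. Unadjusted p-values under 0.05 occurred at 2 CpGs for warm normoxic and 5 for warm hypoxic fish in the permutation test, and at 0 and 4 in limma. The smallest adjusted p of a CpG was 0.121, reached in the warm hypoxic contrast.

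Males and females were compared within the groups. Of the 94 CpGs, 0 passed the threshold in the permutation test and 4 had an unadjusted p under 0.05. The lowest p belonged to position 44947115 of ssa04 (45 Mb), with means of 0.759% in males and 0.414% in females and a difference within groups of 0.483 points (permutation p = 0.00199, adjusted p = 0.187). This CpG is named although it did not pass, and it was chosen after its value was seen. Its difference within groups was 0.386 points without control fish 108, 0.373 without warm hypoxic fish 120 and 0.268 without both (permutation, adjusted p = 0.196, 0.844 and 0.632). Region ssa03 averaged 0.668% in males and 0.714% in females, with a difference within groups of -0.0909 points (permutation p = 0.0248, adjusted p = 0.149). The other regions had adjusted permutation p-values from 0.756 to 0.925.

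Region ssa15 was too shallow to test under the coverage rule, which asked for 30 reads in 6 fish of each group. Its level, over the fish with 30 reads at 80% or more of its CpGs, was 2.12% ± 0.684 in warm normoxic fish of 4 weeks (SD, n = 7) and 1.83% ± 0.376 in warm hypoxic fish of 3 days (SD, n = 5). It was 1.34% ± 0.469 in warm normoxic fish of 3 days (SD, n = 3). Warm hypoxic fish of 4 weeks had a mean of 2.03% (n = 2), control fish of 4 weeks 2.31% (n = 2), and the single control fish of 3 days 1.97%. The higher CpGs of this region lay at 46698630 and 46698648, with 5.86% ± 3.32 and 6.59% ± 4.17 (SD, n = 20 fish).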

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

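Of the tests in this part, those of unconverted cytosines, of read depth (in place of one set beforehand that hardly moved the difference and was void), of the tanks, of variants at single CpGs and of fish that differ over a whole region were chosen only after the result was seen, as were the weighting of the time dependence by reads and the resampling interval given for copied reads.

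The ssa03 level was lower in warm hypoxic than in control fish at 4 weeks, and this difference changed by -0.306 points from 3 days to 4 weeks, or by -0.0156 points with fish weighted by their reads. Cytosines left unconverted throughout the library would move ssa16 by the share lost at ssa03, -0.161 points, or by the same points, -0.252, and the 95% interval at ssa16 reached down only to -0.0199. Region ssa04 (45 Mb) taken alone would allow this, with -0.136 points where that share gives -0.175. A linear trend of level with read depth is argued against, because the mean log10 depth differed by only -0.0927 between warm hypoxic and control fish, so that the trend would need 2.72 points per 10-fold depth, and the slope within groups was 0.0197 points (95% interval from 10000 resamplings of fish -0.0559 to 0.0894). Tanks stay open beside the treatment: in limma on tank means the adjusted p was 0.0103 over the 6 tanks of 4 weeks but 0.0899 over the 12 tank means of both times, and the lower control tank lay 0.211 points above the higher warm hypoxic tank while the 2 warm hypoxic tanks of 3 days differed by 0.214 points, a gap in which sex and tank are mixed, with 4 males in one tank and 1 male and 3 females in the other.

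At ssa04 (35 Mb) the fish of a group differed together at all CpGs. The first component of the deviations from the group means held 74.6% of their variance, against at most 15.7% in 100 shuffled sets, with 18 of 18 CpGs of one sign. A C-to-T variant at single CpGs would leave the other CpGs out of it, but the CpG with the lowest share still had 36.7% of its variance on this component. Few template molecules behind the reads may contribute: the mean squared deviation of deeper over shallower fish was 1.02, which leaves this open because reads are not molecules. Differences between fish in the cells of the liver were not tested.

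In the regions of low level the variance between fish exceeded that of counting, by a factor of 1.94 at ssa03, 8.13 at ssa16, 15.1 at ssa04 (45 Mb) and 70.0 at ssa14. Fish that differ over a whole region were not shown at ssa16, where the first component held 13.1% of the variance. Shuffled sets averaged 11.6% and reached 13.8% there. A weak difference of this kind stays possible, because how small a one this test would show was not examined. At ssa14 the first component held 20.6% against at most 18.5%. Reads that are copies of fewer molecules could be a reason, and would make 10 deep fish (2000 or more reads at ssa03) deviate nearly as much as the other 38. The ratio of their mean squared deviations was 0.457, where counting alone gives 0.180, and lay below 0.590, the bound set beforehand for ruling copies out. That bound left out the counting error that adds to molecule sampling in shallow fish, and the interval from resampling fish, 0.269 to 0.761, holds it, so copies stay open.

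Single fish lay far from the rest of their group in 11 of 75 groups tested with Dixon's ratio of gap to range. Of these groups 42 were of region means and call totals, with 4 such fish where chance, about 1 in 20 groups, gives 2.1. The other 33, with 7 such fish, were of CpGs named for their small p, for which this expectation has no meaning, and the same fish and CpGs recur among the 11. In control fish of 3 days these were ssa04 (45 Mb) with 0.716% in fish 85 (ratio 0.543), ssa14 with 2.90% in fish 84 (0.727), ssa03 position 13688404 with 1.27% in fish 84 (0.619) and ssa04 (45 Mb) position 44947155 with 2.61% in fish 85 (0.767). In warm hypoxic fish of 3 days they were ssa04 (45 Mb) with 0.754% in fish 74 (0.704) and ssa03 position 13688501 with 2.87% in fish 94 (0.544). One warm normoxic fish of 3 days, fish 77, had 87.7% at ssa09 (0.581). At 4 weeks they were position 44947115 of ssa04 (45 Mb) with 3.45% in control fish 108 (0.778) and 2.40% in warm hypoxic fish 120 (0.633), ssa14 position 33502773 with 1.45% in control fish 107 (0.738) and ssa14 position 33502764 with 4.68% in warm normoxic fish 102 (0.679).

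Calls outside the regions were most widespread in warm normoxic fish 101 of 4 weeks, with 194 cytosines against 158 in the highest control fish.

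The counts of CpGs at an unadjusted p under 0.05 were set against 100 splits of the same fish, and chance cannot be excluded for any of them. For warm normoxic against control fish at 3 days, 26 splits gave at least the real count of 7, and the highest other count was 20. For warm hypoxic against control fish it was 23 splits (real 7, highest other 14), and for warm hypoxic against warm normoxic fish 51 (real 5, highest other 12). At 4 weeks the 3 comparisons in the same order gave 59 splits (real 4, highest other 20), 92 (real 2, highest other 19) and 80 (real 3, highest other 14). Between the times it was 77 splits in control (real 3, highest other 19), 76 in warm normoxic (real 3, highest other 19) and 15 in warm hypoxic fish (real 7, highest other 17). For the sexes 61 splits did so (real 4, highest other 18), and for the time dependence 90 with warm normoxic (real 2, highest other 19) and 40 with warm hypoxic fish (real 5, highest other 19). The median of the other splits was 4 or 5 CpGs in each of these, and whether the fish have a structure beyond their groups was not tested with them.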

How the results depend on the processing

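Chosen only after the data were seen were limma with the tank block for region means, leaving out each tank for region means, leaving out the 3 fish with the most calls outside the regions (control fish 84 of 3 days, warm hypoxic fish 120 and warm normoxic fish 101 of 4 weeks), weighting by reads in the time dependence, adjustment over all 54 region tests, limma on tank means, and leaving out each fish that stood apart from its group.

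The ssa03 difference between warm hypoxic and control fish at 4 weeks kept its direction in every alternative run for it, from -0.281 to -0.223 points (adjusted p 0.00186 to 0.0364) and at -0.536 in limma M-values (adjusted p 0.00117 to 0.00151 over fish). With tank means as the unit of limma it passed over the 6 tanks of 4 weeks (-0.536, adjusted p = 0.0103) but not over the 12 tank means of both times (-0.536, adjusted p = 0.0899), which left 0 regions past the threshold, and the cause was not tested. Its change between the times did not keep its size: weighted by reads it was -0.0156 points (permutation, adjusted p = 0.892). That weighting gives the deepest fish, such as control fish 83 and warm hypoxic fish 75 of 3 days, the most weight. Leaving those fish out was not tested. Without the 3 fish with the most calls outside the regions the change was -0.306 points (permutation, adjusted p = 0.0263). The count of CpGs past the threshold was above 0 in 1 of 120 alternatives over 11 settings, with 1 CpG for warm hypoxic against control fish at 3 days in the coverage-weighted model. Of the values at named CpGs, 153 kept direction and side of the threshold and 1, that CpG, came to pass it. The permutation blocked by tank gave 0 CpGs in each of the 3 time comparisons. Keeping strands apart changed nothing, as all calls lay on the plus strand. With a minimum of 100 reads, ssa04 (45 Mb) dropped out of the time dependence for warm hypoxic fish because of control fish 108. Depth limits ssa15 and ssa03, with medians of 18.5 and 436 reads per CpG.

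Calls were gained in these cases. Without the 3 fish, 2 regions passed for warm hypoxic against control fish at 4 weeks, with ssa04 (45 Mb) at -0.162 points (exact permutation, adjusted p = 0.0466). For warm hypoxic against warm normoxic fish 1 region passed, ssa04 (45 Mb) at -0.226 points. Fish 120 was the highest warm hypoxic fish of 4 weeks there (0.611%), so leaving it out widened both differences. Fish 101 was the lowest warm normoxic fish of 4 weeks (0.369%), so leaving it out widened the second. In warm hypoxic fish between the times, 1 region, ssa03, passed in limma with or without the tank block (-0.380 in M-values). It also passed within sex (-0.215 points), and the cause was not tested.

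Differences that turned sign, none past the threshold (smallest adjusted p = 0.237), were as follows, and the cause was not tested. They are in percentage points, except those from limma, which are in M-values. Weighted by coverage, ssa16 was -0.00193 for warm normoxic against control at 3 days, ssa03 -0.233 and -0.104 for warm hypoxic against control and against warm normoxic at 3 days, and ssa03 0.00143 and ssa04 (45 Mb) 0.0470 between the times in warm hypoxic fish. In limma M-values, with or without the tank block and on tank means, ssa04 (45 Mb) was -0.00361 for warm normoxic against control at 3 days, and with or without the block 0.000621 between the times in warm hypoxic fish. Within sex it was -0.00329 and 0.0171 in the same 2 comparisons, ssa09 was 0.111 in the first, and ssa04 (35 Mb) was -0.296 between the times in control. Without the 3 fish, ssa04 (45 Mb) was -0.00123 for warm normoxic and ssa14 0.121 for warm hypoxic against control at 3 days, ssa14 0.105 between the times in control and ssa03 0.00118 in warm normoxic fish. In the time dependence, ssa04 (35 Mb) was 0.0234 for warm normoxic fish without the 3 fish, and ssa04 (45 Mb) 0.0150 for warm hypoxic fish weighted by reads.

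Leaving out each tank, or each fish that stood apart from its group, gave these ranges of differences in points where a sign or call changed. For warm normoxic against control at 3 days they were -0.0896 to 0.0641 at ssa03, -0.0190 to 0.0383 at ssa04 (45 Mb) and -0.786 to 0.380 at ssa09. For warm hypoxic against control at 3 days they were -0.0533 to 0.160 at ssa03 and -0.341 to 0.155 at ssa14, and against warm normoxic -0.0406 to 0.173 at ssa03. At 4 weeks warm normoxic against control gave -1.12 to 1.54 at ssa04 (35 Mb) and -0.0566 to 0.120 at ssa04 (45 Mb). Warm hypoxic against control gave 1 to 2 regions past the threshold and -0.0959 to 0.844 at ssa14. Warm hypoxic against warm normoxic gave -2.51 to 0.152 at ssa04 (35 Mb), -0.214 to 0.726 at ssa14 and -0.00260 to 0.0269 at ssa16. Between the times, control fish gave -0.0220 to 0.154 at ssa04 (45 Mb) and -0.357 to 0.139 at ssa14, and warm normoxic fish -0.0878 to 0.0577 at ssa03 and -1.21 to 1.46 at ssa04 (35 Mb). Warm hypoxic fish gave 0 to 1 regions past the threshold, -0.293 to -0.0794 at ssa03, -0.0387 to 0.0397 at ssa04 (45 Mb) and -0.112 to 0.828 at ssa14.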

Other observations

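None of the values in this part come from tests planned beforehand, and no explanation of them was tested.

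Calls outside the 7 regions occurred in 15 fish, as 525 combinations of a cytosine and a fish. Of the 129 with 10 or more calls, which came from 3 fish, 126 were methylated at 5% or less or at 95% or more. These were 84 at the high and 42 at the low end. The 3 fish with the most such calls were control fish 84 of 3 days with 4029 calls, warm hypoxic fish 120 of 4 weeks with 2072 and warm normoxic fish 101 of 4 weeks with 960.

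Within ssa09 the fish of a group also differed together. The first component of its 8 CpGs held 50.8% of the variance within groups, against at most 26.6% in 100 shuffled sets, and all 8 CpGs had one sign.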
